A study of Mus musculus with 6 samples.

How the data were processed

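RAW 264.7 cells, a mouse macrophage line, were grown for 3 days on zinc alloys coated with calcium phosphate (CaP), and polyadenylated RNA was sequenced from TRIzol lysates with an Illumina TruSeq kit, per the labels' protocols. The 6 libraries form 3 groups of 2, named for the alloy under the cells: CaP Zn, CaP Zn0.8Mn with manganese added, and CaP Zn0.8Mn0.1Li with manganese and lithium added. Groups were taken from the treatment label of each sample and replicate numbers from the sample titles. Nothing in the labels states that the 2 libraries of a group came from separate cultures. P-values for single genes therefore measure only the spread between these libraries, which may be technical.

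The authors deposited whole-number read counts for 54532 genes, with no normalization, and these counts were used for every test unless stated. The same deposited tables give FPKM values, the counts divided by gene length and by a library size that lay between 0.976 and 1.06 times the count total of the same library. The aligner and the counting program are not given in the sources used here. The submitters' processing notes name the mouse build mm9, but 53499 of the 54409 gene identifiers matched to the GENCODE M21 annotation (98.3%) have the start and end of build GRCm38 in the deposited tables. Coordinates are therefore printed as the files give them, as GRCm38 positions, and the conflict with the notes remains. The tables hold 0 columns of samples other than these 6.

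Library totals ran from 14944070 to 17709290 counts, so that a floor of 3 counts corresponds to 0.169 to 0.201 CPM, counts scaled to library size. Floors cover counting error only, since the reads carry no molecular identifiers. Values per library are CPM scaled with TMM factors, which lay between 0.973 and 1.05, and group values are means with the SD of 2 libraries. Within groups, the counts of the 2 libraries differed by more than sampling noise, with a chi-square per gene of 11.7 for CaP Zn, 283 for CaP Zn0.8Mn and 6.17 for CaP Zn0.8Mn0.1Li. This only speaks against a library deposited more than once. Separate preparation alone would exceed that noise, so it does not show separate cultures. Each library was counted as a replicate because its label numbers it as one.

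Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM, genes kept by filterByExpr), which left 13156 genes, a group-means model over all 6 libraries and 3 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and log2 fold changes written as the first-named group over the second. The 3 pairs of alloys were compared, and an F test covered the 3 alloys together. Of 40 gene lists written for macrophages, metals and bone, the 35 with at least 5 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 3 and a preset correlation of 0.01 between genes. Camera compares a list with all other genes. At a preset correlation its p-values rest mainly on the spread between genes, not between libraries. Its calls were repeated with a correlation estimated per list and with fry. The estimated correlation leaves camera the few residual degrees of freedom, so a list it did not call is not shown to be unchanged. For each list, single genes were also adjusted over the list alone.

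The groups, tests, gene lists, most alternative settings and the rule for naming genes were fixed before the data were examined. That rule names, in each comparison, the 8 largest rises and 8 largest falls among called genes of at least 5 CPM with non-overlapping libraries, then the 3 called members of lowest adjusted p in each called list or list with at least 3 called members. It also names 20 genes whatever their result: Mt1, Mt2, Slc30a1, Nos2, Tnf, Il1b, Il6, Cd86, Arg1, Mrc1, Il10, Tgfb1, Bmp2, Vegfa, Osm, Acp5, Ctsk, Sod2, Hmox1 and Axin2. Because no gene was called with all 6 libraries, the first parts of the rule named none. A second rule was set after the data were seen: in every list called with 6 libraries or without CaP Zn0.8Mn replicate 1, examples come from the 4 members of at least 5 CPM with the largest absolute log2 fold change. Other genes named in the text were chosen after their values were seen, and this is said where they appear.

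Alternatives fixed in advance were size factors by relative log expression (RLE), library totals only, DESeq2 1.42.0, limma-voom, no filter or a mean count of at least 100, the replicate number as a block, only the libraries compared, a 2-fold minimum, log2(FPKM + 1) and log2(FPKM + 0.1) with limma for genes of mean FPKM at least 1, mitochondrial genes left out, and each library left out in turn. After the values were seen, limma-voom with quality weights, DESeq2, limma-voom, a new filter and the estimated correlation on 5 libraries (without CaP Zn0.8Mn replicate 1), and a fit to 4 libraries without CaP Zn replicate 1 as well were added. The edgeR step was tested on simulated counts for 13156 genes, with known changes between CaP Zn0.8Mn0.1Li and CaP Zn. With the spread of all 6 libraries it recovered 0% of 1.5-fold, 0% of 2-fold and 36.4% of 4-fold changes, with 2 false calls. With the spread of the 5 libraries it recovered 58.2%, 77.6% and 92.4%, with 11 false calls. Camera at the preset correlation recovered the raised list both times, among genes drawn independently of each other. Every library was drawn with the same spread per gene, while in the data CaP Zn0.8Mn replicate 1 stood apart. The rates with 6 libraries therefore hold for that simulated setting only. Because all pairs of alloys share libraries, the correlation between the comparisons against CaP Zn was set beside 100 simulated draws with no effect.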

Results

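Gene expression was measured by RNA sequencing in RAW 264.7 macrophages, a line derived from a mouse leukaemia-virus tumour, after 3 days on calcium phosphate-coated zinc (CaP Zn), on the same coating over zinc with manganese (CaP Zn0.8Mn), or over zinc with manganese and lithium (CaP Zn0.8Mn0.1Li). The study asked how these implant materials bear on the polarization of macrophages, the shift between inflammatory (M1) and repair-associated (M2) states, in surroundings where bone forms. Each alloy had 2 libraries. Total counts were 17709290 and 15874516 on CaP Zn, 14944070 and 15910925 on CaP Zn0.8Mn, and 16993937 and 16345256 on CaP Zn0.8Mn0.1Li. Between 18334 and 18820 genes had at least 1 count in a library.

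CaP Zn0.8Mn replicate 1 stood apart from the other 5 libraries. Mitochondrial genes took 7.88% of its counts, against 1.82% to 2.15% elsewhere. Mitochondrial rRNA took 0.350%, against 0.0361% to 0.0615%. Across genes, its log2 CPM correlated with the other libraries at r = 0.903 to 0.922, while the other 5 correlated with each other at 0.989 to 0.992 (genes are not independent replicates). Among 7862 genes of at least 20 CPM, 983 were over 2-fold higher and 1171 over 2-fold lower there than in the mean of the others. Each other library had at most 4 and 6 such genes. The median of the 12 mitochondrially encoded mRNAs was 3.49 log2 units above the other 5 libraries, and core macrophage genes (0.72) and genes for calcium and phosphate sensing (0.83) were also higher. Summed CPM of the core macrophage list, however, was 0.852 times the mean sum of the other 5 libraries. Of its 24 tested members, 10 were over 2-fold higher and 3 over 2-fold lower. Medians were lower for pro-inflammatory cytokines and chemokines (-2.16), M1 markers (-1.67), p53 targets (-1.36) and cytosolic ribosomal proteins (-1.10). These medians come from 1 library, each outside 99% of 10000 random lists matched on expression, and its values enter every CaP Zn0.8Mn mean below.

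Of the 20 genes named in advance, 15 were expressed well enough to test, and none passed the threshold in any comparison. Nos2 (ENSMUSG00000020826, chromosome 11: 78920787 to 78960254, plus strand), the inducible nitric oxide synthase of inflammatory macrophages, had a mean of 109 ± 3.81 CPM on CaP Zn, 59.4 ± 71.6 on CaP Zn0.8Mn and 107 ± 0.499 on CaP Zn0.8Mn0.1Li (SD, n = 2 each). The CaP Zn0.8Mn libraries read 8.79 and 110 CPM, so the lower mean came from replicate 1. Tnf (ENSMUSG00000024401, chromosome 17: 35199381 to 35202007, minus strand), which encodes tumour necrosis factor, read 112 and 150 CPM on CaP Zn, 14.0 and 153 on CaP Zn0.8Mn and 154 and 147 on CaP Zn0.8Mn0.1Li. Osm, a macrophage cytokine that acts on bone-forming cells, read 2.11 CPM in the same library and 14.7 to 21.2 elsewhere. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, read 6.01 CPM there and 36.8 to 52.1 elsewhere. Hmox1, the stress-induced heme oxygenase, read 62.7 and 178 to 222. Cd86, a costimulatory molecule counted among M1 markers, went the other way, with 9.91 and 3.81 CPM on CaP Zn0.8Mn, 2.26 and 2.43 on CaP Zn and 4.47 and 4.22 on CaP Zn0.8Mn0.1Li. Metallothionein Mt1 (ENSMUSG00000031765, chromosome 8: 94179082 to 94180327, plus strand), which binds zinc, had means of 297 ± 30.9 CPM on CaP Zn, 279 ± 176 on CaP Zn0.8Mn and 424 ± 76.8 on CaP Zn0.8Mn0.1Li. The zinc exporter gene Slc30a1 lay between 25.9 and 35.4 CPM in all 6 libraries. Its log2 difference between CaP Zn0.8Mn0.1Li and CaP Zn, 0.0056, turned to -0.036 when scaled by library totals only. Arg1, the arginase of M2 cells, was near the limit of detection at 0.0661 to 0.856 CPM. The untested genes were Il6 (0 to 4 counts per library), Il10 (3 to 7), Bmp2 (0 to 4), the mannose receptor gene Mrc1 (52 counts in CaP Zn0.8Mn replicate 1 and 2 to 9 elsewhere) and the Wnt target Axin2, whose 0 counts allow at most 0.201 CPM in a library. Adjusted p for the tested genes ranged from 0.773 to 0.937 for CaP Zn0.8Mn against CaP Zn, was 1.00 for CaP Zn0.8Mn0.1Li against CaP Zn, and ranged from 0.680 to 0.877 for CaP Zn0.8Mn0.1Li against CaP Zn0.8Mn.

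**Figure D1:**
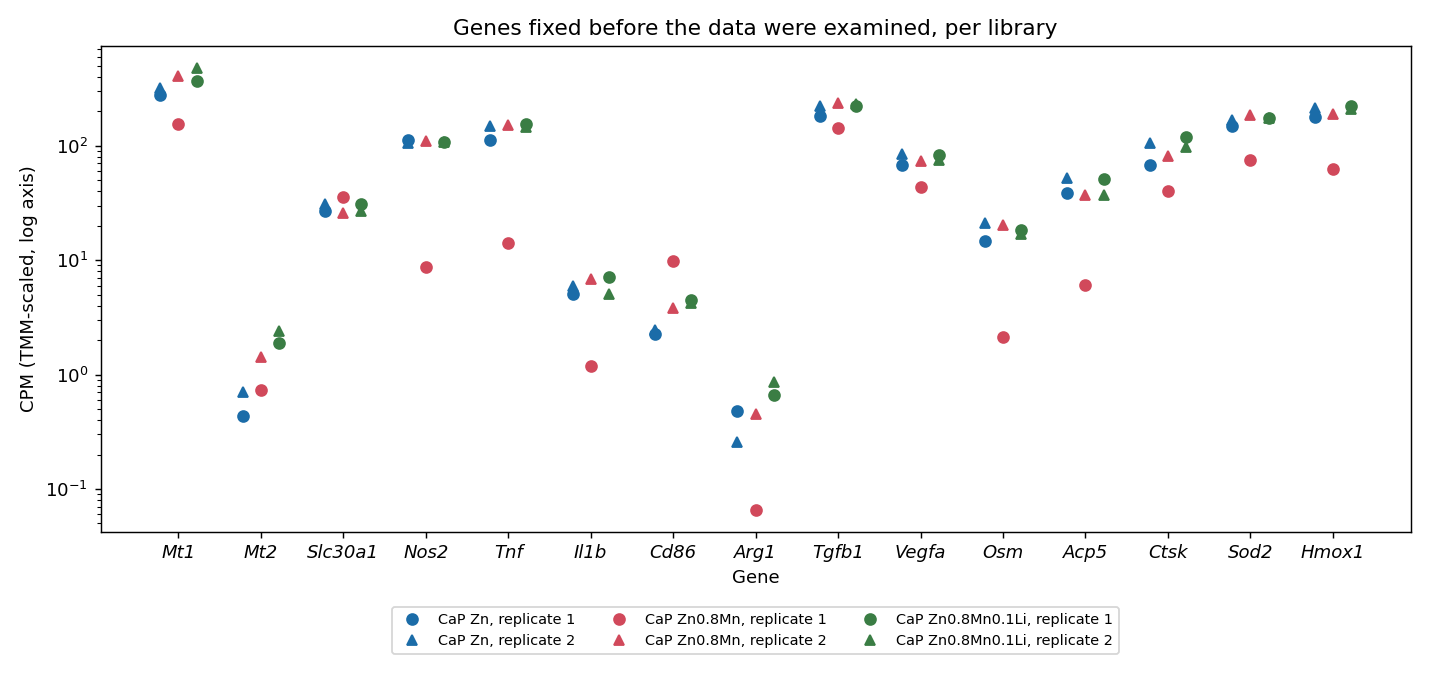
Expression of the 15 tested genes named in advance, as TMM-scaled CPM on a log axis, with 1 point per library and colours for the 3 alloys. In CaP Zn0.8Mn replicate 1, Nos2 sits at 8.79 CPM, below 106.5 to 112 CPM in the other 5 libraries.

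CaP Zn0.8Mn was compared with CaP Zn to see what manganese in the alloy changed. With all 6 libraries, camera at the preset correlation called the inflammatory lists lower on CaP Zn0.8Mn: 15 of 17 M1 markers were lower (median log2 fold change -0.87, adjusted p = 0.0127) and 15 of 19 pro-inflammatory cytokines and chemokines (-1.18, adjusted p = 0.00265). For each of the 13 lists it called, the adjusted p was 0.750 with an estimated correlation, and without CaP Zn0.8Mn replicate 1 the medians of these inflammatory lists were 0.15 and 0.23, neither of them called. Ptgs2, the inducible cyclooxygenase, read 141 and 163 CPM on CaP Zn against 22.1 and 142 on CaP Zn0.8Mn (log2 fold change -0.89, SE 0.78). The neutrophil chemokine gene Cxcl2 read 127 and 140 against 5.15 and 156. The NF-kB targets (18 of 24 lower, -0.42, adjusted p = 0.0425), interferon-stimulated genes (23 of 31, -0.29, adjusted p = 0.0440) and p53 targets (16 of 19, -0.63, adjusted p = 0.0102) were called lower too, again with 0.750 as adjusted p with an estimated correlation. The p53 target Cdkn1a, a cell cycle inhibitor, read 657 and 777 against 176 and 751 CPM. Called lower as well were cytosolic ribosomal proteins (47 of 52 lower, -0.49, adjusted p = 9.27e-05), nuclear genes of oxidative phosphorylation (31 of 36, -0.37, adjusted p = 0.00135) and cholesterol synthesis genes (20 of 23, -0.20, adjusted p = 0.0440). The mitochondrially encoded mRNAs were called higher (12 of 12, 1.75, adjusted p = 1.08e-04), as were core macrophage genes (18 of 24, 0.47, adjusted p = 0.00829), M2 markers (12 of 16, 0.43, adjusted p = 0.0440), genes of lipid uptake and cholesterol efflux (16 of 23, 0.35, adjusted p = 0.0440) and genes of calcium and phosphate sensing (17 of 20, 0.35, adjusted p = 0.0111). For these lists too the adjusted p was 0.750 with an estimated correlation. That test called 0 of the 35 lists, and fry called 0. The estimated correlation rested on 3 residual degrees of freedom, so the absence of a call does not show that a list was unchanged. In the lists called higher, the fractalkine receptor gene Cx3cr1 read 24.7 and 19.2 CPM on CaP Zn against 592 and 26.8 on CaP Zn0.8Mn. The beta-glucan receptor gene Clec7a read 6.83 and 7.80 against 117 and 10.1, the cholesterol transporter gene Abca1 12.7 and 13.8 against 108 and 8.98, and the calcium pump gene Atp2b1 206 and 212 against 556 and 200. Lists for zinc and metal handling (median 0.09, adjusted p = 0.441), osteogenic and angiogenic secreted factors (-0.13, adjusted p = 0.671) and osteoclast genes (0.0087 with the test pointing down, adjusted p = 0.844) did not pass.

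No single gene passed in that comparison with edgeR (0 of 13156, with 207 at an unadjusted p under 0.05). DESeq2 called 1 and limma-voom 0. The DESeq2 call was the glycolytic enzyme gene Gapdh (log2 fold change -4.13, adjusted p = 8.06e-17), chosen after its values were seen. With edgeR its adjusted p was 0.773, and it was the 1 gene in any list that passed when adjusted over the list alone. Gapdh has near-identical copies in the genome that can share its reads. Summed over Gapdh and all genes that share a 50-base stretch with it, the libraries read 1855 and 2389 CPM on CaP Zn, 938 and 1887 on CaP Zn0.8Mn and 2158 and 2579 on CaP Zn0.8Mn0.1Li. The list calls followed CaP Zn0.8Mn replicate 1, the library with 7.88% mitochondrial counts. Without it, 10 lists were called and all were higher, each with an adjusted p of 0.886 with an estimated correlation. M2 markers (0.20, adjusted p = 0.0431) and core macrophage genes (0.20, adjusted p = 0.00125) kept their direction. Oxidative phosphorylation (0.09, adjusted p = 0.00533), cholesterol synthesis (0.10, adjusted p = 0.0319) and ribosomal proteins (0.12, adjusted p = 0.00291) were called the opposite way. Medians for M1 markers (0.15), cytokines (0.23), p53 targets (0.084) and calcium and phosphate sensing (-0.024) changed sign. That for mitochondrial mRNAs (-0.061) changed sign while the mean (0.022) and the test did not. The other 5 lists called without that library included antigen presentation (14 of 14 higher, 0.16, adjusted p = 0.00125), superoxide and peroxide enzymes (17 of 18, 0.15, adjusted p = 0.00125) and lysosome and autophagy (25 of 34, 0.12, adjusted p = 0.00492). Among them also were unfolded protein response and ATF4 targets (23 of 26, 0.12, adjusted p = 0.0225) and iron and heme handling (10 of 15, 0.10, adjusted p = 0.0431). For these lists too the adjusted p was 0.886 with an estimated correlation. Their members with the largest differences included the proteasome subunit gene Psmb8 (log2 fold change 0.39, SE 0.10), the lysosomal proteases Ctsd (0.50, SE 0.16) and Ctsl (0.41, SE 0.14), and Lcn2, an iron-siderophore binding protein (1.78, SE 0.45). When adjusted over the list alone, that fit called the macrophage genes Itgam (0.48), Mpeg1 (0.41) and Adgre1 (0.41), with Psmb8, Csf3 (1.14), Gstp1 (0.73), Cd36 (0.41) and mt-Atp6 (0.66) in other lists. The edgeR test over all genes then called 2, both lower and both chosen after their values were seen: the processed pseudogene Gm10123 (ENSMUSG00000062933, chromosome 9: 96895658 to 96896147, plus strand; -1.22, SE 0.15, adjusted p = 0.00907) and Rpl7a-ps5, a pseudogene of a ribosomal protein gene (-0.81, SE 0.12, adjusted p = 0.0388), both of which can share reads with copies. Leaving out CaP Zn0.8Mn replicate 2 instead gave 7808 genes and 14 lists, and leaving out either CaP Zn0.8Mn0.1Li library gave 8 lists, without M2 markers, NF-kB targets, interferon-stimulated genes, cholesterol synthesis and lipid uptake (adjusted p = 0.0513 to 0.0592). Besides replicate 1, the calls of M1 markers, cytokines, p53 targets, oxidative phosphorylation, mitochondrial mRNAs and ribosomal proteins did not need any 1 library. Omitting CaP Zn replicate 1 ended those of M2 markers (adjusted p = 0.140), interferon-stimulated genes (0.662), lipid uptake (0.133), calcium sensing (0.0507) and core macrophage genes (0.0868). Omitting CaP Zn replicate 2 ended those of NF-kB targets (0.136) and cholesterol synthesis (0.194). Omitting CaP Zn0.8Mn replicate 2 ended the calls of M2 markers (0.242), interferon-stimulated genes (0.103) and lipid uptake (0.103).

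**Figure D2:**
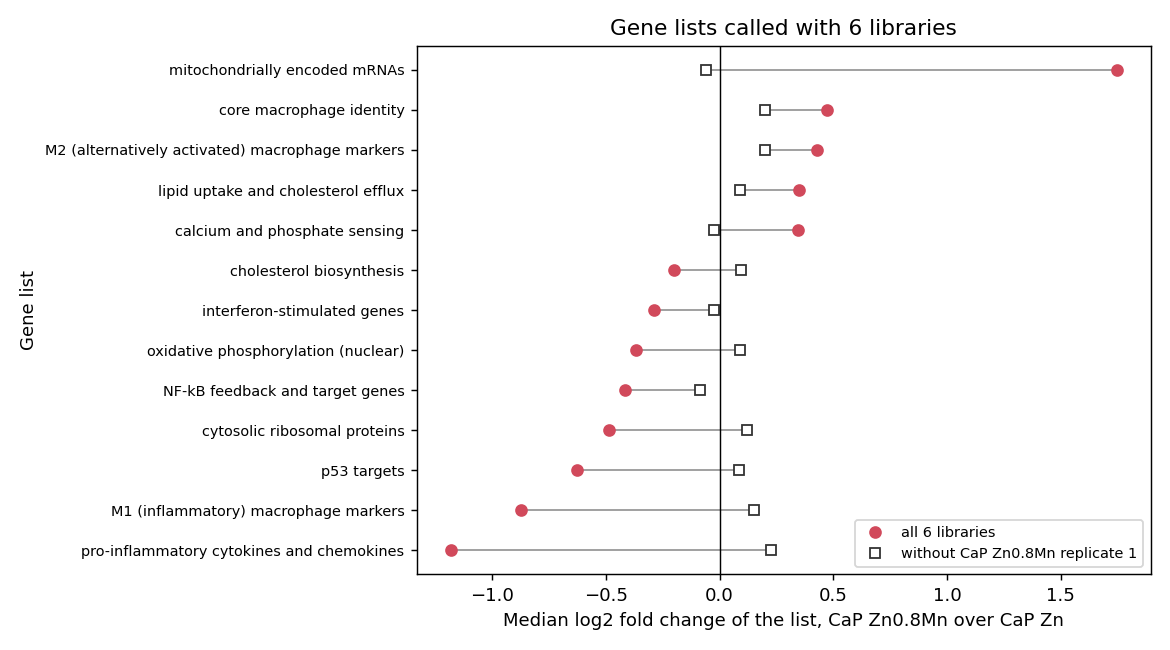
Median log2 fold change, CaP Zn0.8Mn over CaP Zn, of the 13 lists that camera called with 6 libraries, with filled circles for all 6 libraries and open squares without CaP Zn0.8Mn replicate 1. Mitochondrially encoded mRNAs move from 1.75 to -0.061 and cytosolic ribosomal proteins from -0.49 to 0.12.

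CaP Zn0.8Mn0.1Li was compared with CaP Zn to see what manganese and lithium changed together. With all 6 libraries, camera called interferon-stimulated genes lower (28 of 31, median log2 fold change -0.18, camera adjusted p = 0.00537, and 0.919 as adjusted p with an estimated correlation). Ifi44, an interferon-induced gene, read 139 and 80.8 CPM on CaP Zn against 73.7 and 77.5 on CaP Zn0.8Mn0.1Li (log2 fold change -0.54, SE 0.28). Rtp4, another, read 20.5 and 11.3 against 10.5 and 9.84 (-0.65, SE 0.36). M2 markers were called higher (12 of 16, 0.19, adjusted p = 0.0166, and 0.731 as adjusted p with an estimated correlation), among them the lectin gene Clec10a at 5.97 and 7.93 against 11.2 and 10.4 CPM and the interleukin 1 receptor antagonist gene Il1rn at 35.0 and 32.9 against 40.8 and 41.2. Genes of extracellular matrix and adhesion were called higher (17 of 26, 0.09, adjusted p = 0.0121, and 0.731 as adjusted p with an estimated correlation). These 3 calls were lost without CaP Zn replicate 1. Among the matrix and adhesion genes were the gelatinase gene Mmp9 at 26.6 and 45.9 against 73.6 and 82.7 CPM, osteopontin (Spp1) at 9148 and 9749 against 12651 and 14905, and the integrin subunit gene Itgam at 97.1 and 104 against 140 and 136. Neither the estimated correlation nor fry called any list. Zinc and metal handling (14 of 25 higher, 0.017, adjusted p = 0.361), osteogenic and angiogenic factors (0.027, adjusted p = 0.726) and osteoclast genes (2.4e-04, adjusted p = 0.407) did not pass. Of lists on the textbook targets of lithium, Wnt/beta-catenin targets had 6 of 10 members higher (median 0.041, mean -0.051 with the test down, adjusted p = 0.726), and inositol phosphate enzymes had a median of 0.0095 (adjusted p = 0.726). The Wnt list is a weak readout of GSK3 inhibition here. Only 10 of its 24 members were tested, Axin2 had 0 counts, and the list also holds the pathway genes Ctnnb1, Gsk3a and Gsk3b.

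In the same comparison 0 genes passed with edgeR, where 29 had an unadjusted p under 0.05, and with DESeq2 and limma-voom, and 0 when adjusted over the list alone. The spread of CaP Zn0.8Mn replicate 1 entered this test through the shared estimate. Without that library, 660 genes had an unadjusted p under 0.05 and still 0 passed with edgeR, the lowest adjusted p being 0.0934 for Csf3, a granulocyte growth factor gene (log2 fold change 1.33, 5.32 and 5.44 against 11.5 and 15.5 CPM; chosen after its values were seen). DESeq2 on those 5 libraries called 12, of which 9 were higher, and limma-voom 0. Camera on those 5 libraries called 9 lists, each with an adjusted p of 0.824 with an estimated correlation. They were the 3 above, the mitochondrial mRNAs (11 of 12 lower, -0.25, adjusted p = 3.73e-04) and others that were higher. The higher lists were p53 targets (18 of 19, 0.13, adjusted p = 0.00877), antigen presentation (12 of 14, 0.14, adjusted p = 0.00877), iron and heme handling (12 of 15, 0.09, adjusted p = 0.0291), ribosomal proteins (44 of 52, 0.08, adjusted p = 0.0291) and lysosome and autophagy (26 of 34, 0.08, adjusted p = 0.0367). For these lists too the adjusted p was 0.824 with an estimated correlation. When adjusted over the list alone, edgeR on those libraries called Mt2 (1.92, SE 0.45), Mt1 (0.51, SE 0.12) and the metal transporter gene Slc11a1 (0.28, SE 0.09) among zinc and metal handling. Counts of Mt2 were low, at 8 and 11 on CaP Zn against 31 and 39 on CaP Zn0.8Mn0.1Li. That test also called Csf3, Ccl2 (0.72, SE 0.16) and Ccl6 (1.03, SE 0.27) among cytokines, and Ccl2 and Cd86 (0.89, SE 0.27) among M1 markers. It further called Itgam, Adgre1 (0.29), Cx3cr1 (-0.66) and Cebpa (-0.61) among core macrophage genes, Ddit3 (0.47) among ATF4 targets, and 5 genes each of extracellular matrix and adhesion and of mitochondrial mRNAs. Those of matrix and adhesion, chosen after their values were seen, were the integrins Itgam (0.46), Itgb7 (0.77) and Itgb2 (0.36), Adam8 (0.30) and Itga4 (-0.38). Those of mitochondrial mRNAs were mt-Nd1 (-0.68), mt-Nd2 (-0.50), mt-Cytb (-0.47), mt-Nd4 (-0.33) and mt-Nd6 (-0.22). Without CaP Zn replicate 1, 0 lists were called with the other 5 libraries. The median of interferon-stimulated genes then shrank to -0.061 (adjusted p = 0.905), while M2 markers kept 0.17 (adjusted p = 0.259) and matrix and adhesion genes had 0.053 (adjusted p = 0.194). Without CaP Zn0.8Mn0.1Li replicate 1, 0 lists were called as well, with medians of -0.19 (adjusted p = 0.0957), 0.23 (adjusted p = 0.0957) and 0.041 (adjusted p = 0.211) for these lists. Without CaP Zn replicate 2 there were 7, without CaP Zn0.8Mn replicate 2 there were 10, and without CaP Zn0.8Mn0.1Li replicate 2 there were 3, with M2 markers lost (adjusted p = 0.0847).

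CaP Zn0.8Mn0.1Li was compared with CaP Zn0.8Mn to see what lithium added. With all 6 libraries, camera called pro-inflammatory cytokines and chemokines higher on CaP Zn0.8Mn0.1Li (19 of 19, median log2 fold change 1.00, adjusted p = 1.28e-04), with M1 markers (14 of 17, 0.94, adjusted p = 0.0107) and p53 targets (17 of 19, 0.82, adjusted p = 0.00213). For each of the 8 lists it called, the adjusted p was 0.708 with an estimated correlation, and without CaP Zn0.8Mn replicate 1 the cytokines had 8 of 19 members higher (median -0.023, adjusted p = 0.876). The chemokine gene Ccl3 read 80.1 and 905 CPM on CaP Zn0.8Mn against 930 and 836 on CaP Zn0.8Mn0.1Li. Ccl2, the monocyte chemoattractant gene, read 6.67 and 11.5 against 15.4 and 18.8 (log2 fold change 0.91, SE 0.33). Ribosomal proteins (48 of 52, 0.59, adjusted p = 1.43e-05), oxidative phosphorylation (34 of 36, 0.39, adjusted p = 3.48e-04) and cholesterol synthesis (21 of 23, 0.30, adjusted p = 0.0196) were called higher, with the ribosomal gene Rps28 at 41.5 and 453 against 463 and 493 CPM. Mitochondrially encoded mRNAs were called lower (12 of 12, -2.04, adjusted p = 3.88e-05), with mt-Nd1, a subunit of respiratory complex I, at 8462 and 585 against 402 and 424 CPM, and so were genes of calcium and phosphate sensing (16 of 20, -0.45, adjusted p = 0.0117). For these lists too the adjusted p was 0.708 with an estimated correlation, and neither that test nor fry called any. Wnt/beta-catenin targets had 3 of 10 members higher (median -0.27, mean 0.023 with the test down, adjusted p = 0.457), and inositol phosphate enzymes had a median of -0.092 (adjusted p = 0.590). With edgeR 0 genes passed, with 316 at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 called 3: Gapdh (4.62), the RNA sensor gene Tlr7 (-5.28) and Cx3cr1 (-4.47), chosen after their values were seen. When adjusted over the list alone, only Gapdh passed, among hypoxia and glycolysis genes. CaP Zn0.8Mn replicate 1, with its 7.88% of mitochondrial counts, carried most of these list calls. Without it 2 lists were called, mitochondrial mRNAs (11 of 12 lower, -0.36, adjusted p = 7.13e-05) and core macrophage genes (20 of 24 lower, -0.10, adjusted p = 0.0287), both with an adjusted p of 0.955 with an estimated correlation. Cx3cr1, at 26.8 CPM in the remaining CaP Zn0.8Mn library against 13.2 and 14.7, was the 1 macrophage gene that passed when adjusted over the list alone (-0.95, SE 0.18), and mt-Co2, mt-Atp6, mt-Nd1, mt-Cytb and mt-Nd2 passed in the mitochondrial list. The medians of ribosomal proteins (-0.054), oxidative phosphorylation (-0.055), cholesterol synthesis (-0.039), M1 markers (-0.037), cytokines (-0.023), p53 targets (-0.0078) and calcium sensing (0.0095) then had the opposite sign, and the tests of the last 4 kept theirs. Without that library edgeR called Gm10123 (1.10, adjusted p = 0.0197) and the mitochondrial rRNA gene mt-Rnr2 (-0.83, adjusted p = 0.0197), chosen after their values were seen. Without CaP Zn0.8Mn replicate 2 it called 8096 genes.

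Over the 3 alloys together, edgeR's F test called 0 genes, with 139 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 4 (Gapdh, Tlr7, Adgre5 and Cx3cr1, chosen after their values were seen). Without CaP Zn0.8Mn replicate 1 the F test called 1 gene, Gm10123 (adjusted p = 0.0311), at 905 and 902 CPM on CaP Zn, 387 in the remaining CaP Zn0.8Mn library and 748 and 913 on CaP Zn0.8Mn0.1Li. Without CaP Zn0.8Mn replicate 2 it called 7603. The comparisons of CaP Zn0.8Mn and of CaP Zn0.8Mn0.1Li with CaP Zn each called 0 genes with 6 libraries, so their overlap of 0 carries no information. Across genes, their log2 fold changes correlated at r = -0.015 with 6 libraries, against a mean of 0.498 in simulated draws with no effect. The draws gave every library the same spread per gene. In the data the wide spread lay in CaP Zn0.8Mn replicate 1 (SD of log2 ratios 1.01, against 0.124 to 0.183 elsewhere). The 6-library value set beside those draws therefore says nothing about the alloys. With 5 libraries r was 0.441, against a simulated mean of 0.398 and a highest value of 0.436. The covariance with 5 libraries was 0.0344, against 0.0267 simulated, a difference of 0.0077. A split of the control would leave 1 CaP Zn library on each side and was not made, so part of the excess may come from the shared libraries.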

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

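Each alloy had 2 libraries, 1 of which, CaP Zn0.8Mn replicate 1, differed from the rest, so the spread estimated from all 6 libraries was wide (biological coefficient of variation 30.7%, against 8.10% without it). Where a group was left with a lone library, its spread was assumed to be that of the other groups. Where the text below does not name a cause, the cause was not tested. No gene value whose sign differed from that of the 6-library fit had passed the threshold in either fit. Some values of genes named in advance kept their sign and passed in an alternative, though not with 6 libraries. The comparisons are written as CaP Zn0.8Mn over CaP Zn, CaP Zn0.8Mn0.1Li over CaP Zn and CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn, in that order unless named.

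Genes called with all 6 libraries numbered 0, 0 and 0, and 0 over the 3 alloys. The counts stayed at 0 in all 4 with RLE, library totals only, limma-voom, a mean count of at least 100, a 2-fold minimum, log2(FPKM + 1), log2(FPKM + 0.1), mitochondrial genes left out and quality weights. The quality weights were 0.1185 for CaP Zn0.8Mn replicate 1 and 0.1174 for replicate 2. They therefore did not set replicate 1 apart from replicate 2. DESeq2 called 1, 0 and 3 genes and 4 over the 3 alloys. Without a filter edgeR called 1, 0 and 1, and 1 over the 3 alloys, each time Gapdh. Leaving out each library in turn gave a lowest of 0 and a highest of 7808 genes for CaP Zn0.8Mn over CaP Zn, 0 and 0 for CaP Zn0.8Mn0.1Li over CaP Zn, 0 and 8096 for CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn, and 0 and 7603 over the 3 alloys. The highest values came without CaP Zn0.8Mn replicate 2, a fit in which CaP Zn0.8Mn is the lone library that stands apart. Without CaP Zn0.8Mn replicate 1 the counts were 2, 0 and 2, and 1 over the 3 alloys. On the same 5 libraries DESeq2 called 5, 12 and 3, and 10 over the 3 alloys, limma-voom 1, 0 and 2, and 1, and edgeR with the filter redone 2, 1 and 4, and 5. With CaP Zn replicate 1 left out as well, 4 libraries gave 43, 47 and 40 genes, and 91 over the 3 alloys. In that fit CaP Zn and CaP Zn0.8Mn had 1 library each, so the spread came from the 2 CaP Zn0.8Mn0.1Li libraries alone. Those 4-library counts therefore do not show that more genes differed between the alloys.

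Lists called with all 6 libraries numbered 13, 3 and 8. RLE gave 13, 3 and 8, library totals only 12, 3 and 9, and a mean count of at least 100 gave 13, 10 and 10. Camera with an estimated correlation called 0 in each comparison, and fry 0. The former had few residual degrees of freedom, so its result does not show that the lists were unchanged. Leaving out each library gave a lowest of 8 and a highest of 14 lists for CaP Zn0.8Mn over CaP Zn, 0 and 10 for CaP Zn0.8Mn0.1Li over CaP Zn, and 2 and 11 for CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn. The estimated correlation on 5 libraries called 0, 0 and 0, and the preset correlation on 4 libraries called 1, 3 and 3. Interferon-stimulated genes in CaP Zn0.8Mn over CaP Zn lost their call with library totals only (adjusted p = 0.0590).

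Replicate numbers were tested as a block although nothing says that equal numbers share a batch. Deviations of the first libraries correlated across genes at 0.263, -0.162 and -0.0947 for the 3 pairs of alloys. Equal numbers thus went together weakly for CaP Zn and CaP Zn0.8Mn, and not for the pairs with CaP Zn0.8Mn0.1Li. With the replicate block 0 genes were called in every comparison, and 11, 3 and 10 lists. In CaP Zn0.8Mn over CaP Zn the replicate block ended the calls of M2 markers (adjusted p = 0.0505), lipid uptake and cholesterol efflux (0.0919) and interferon-stimulated genes (0.0894), and kept the other 10 of the 13. In CaP Zn0.8Mn0.1Li over CaP Zn the replicate block moved Slc30a1 to -0.0052, Osm to 0.097 and Acp5 to 0.080.

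The 5-library fits (edgeR, DESeq2, limma-voom and the filter redone) turned the sign of several genes named in advance, because the CaP Zn0.8Mn mean is then that of replicate 2. For CaP Zn0.8Mn over CaP Zn they gave Mt1 0.44, Slc30a1 -0.16 to -0.15, Nos2 0.011 to 0.013, Tnf 0.22 to 0.24, Il1b 0.31 to 0.32, Arg1 0.26, 0.28 and 0.31, Tgfb1 0.22 to 0.23, Osm 0.18 to 0.22 and Sod2 0.22. For CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn they gave Slc30a1 0.17, Nos2 -0.040 to -0.039, Tnf -0.024 to -0.023, Il1b -0.18 to -0.16, Cd86 0.19, Tgfb1 -0.043 to -0.042, Osm -0.19 and Sod2 -0.085. In CaP Zn0.8Mn0.1Li over CaP Zn, limma-voom on 5 libraries gave Osm 0.025. List medians without CaP Zn0.8Mn replicate 1, with either correlation, for CaP Zn0.8Mn over CaP Zn were M1 markers 0.15, cytokines 0.23, p53 targets 0.084, oxidative phosphorylation 0.091, cholesterol synthesis 0.096, calcium and phosphate sensing -0.024 and ribosomal proteins 0.12. For CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn they were oxidative phosphorylation -0.055, cholesterol synthesis -0.039 and ribosomal proteins -0.054.

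With 4 libraries, CaP Zn0.8Mn over CaP Zn gave Mt1 0.34, Slc30a1 -0.26, Nos2 0.049, Tnf 0.031, Il1b 0.21, Arg1 0.81, Tgfb1 0.093 and Sod2 0.15. CaP Zn0.8Mn0.1Li over CaP Zn gave Slc30a1 -0.094, Nos2 0.0072 and Vegfa -0.099, and CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn gave Slc30a1 0.17, Nos2 -0.042, Tnf -0.026, Il1b -0.16, Cd86 0.18, Tgfb1 -0.045, Osm -0.19 and Sod2 -0.087. List medians for CaP Zn0.8Mn over CaP Zn were M1 markers 0.091, cytokines 0.10, interferon-stimulated genes 0.11, p53 targets 0.055, oxidative phosphorylation 0.059, cholesterol synthesis 0.047 and calcium and phosphate sensing -0.036. For CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn they were M1 markers -0.040, oxidative phosphorylation -0.058, cholesterol synthesis -0.042 and ribosomal proteins -0.057.

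Without CaP Zn0.8Mn replicate 2 the same genes lay at the other end, because the lone CaP Zn0.8Mn library is then replicate 1. CaP Zn0.8Mn over CaP Zn gave Mt1 -0.95, Slc30a1 0.28, Nos2 -3.64, Tnf -3.23, Il1b -2.22, Arg1 -2.39, Tgfb1 -0.51, Osm -3.09 and Sod2 -1.10, and CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn gave Slc30a1 -0.28, Nos2 3.61, Tnf 3.42, Il1b 2.36, Cd86 -1.19, Tgfb1 0.69, Osm 3.06 and Sod2 1.22. List medians for CaP Zn0.8Mn over CaP Zn were M1 markers -1.52, cytokines -2.06, p53 targets -1.29, oxidative phosphorylation -0.79, cholesterol synthesis -0.57, calcium and phosphate sensing 0.81 and ribosomal proteins -1.06. For CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn they were oxidative phosphorylation 0.81, cholesterol synthesis 0.70 and ribosomal proteins 1.13.

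Other changes of sign came with single libraries left out or other settings. For CaP Zn0.8Mn over CaP Zn, Mt1 was 0.020 and Tgfb1 0.049 without CaP Zn replicate 2, and Arg1 was 0.023 and Slc30a1 -0.023 without CaP Zn replicate 1. For CaP Zn0.8Mn0.1Li over CaP Zn0.8Mn, Slc30a1 was 0.033 without CaP Zn0.8Mn0.1Li replicate 2. For CaP Zn0.8Mn0.1Li over CaP Zn, Slc30a1 was -0.0064 without a filter and -0.036 with library totals only, its lowest and highest with a library left out being -0.12 (without CaP Zn0.8Mn0.1Li replicate 1) and 0.11 (without CaP Zn replicate 2). Osm was 0.017 with limma-voom, 0.0039 with log2(FPKM + 1), 0.0067 with log2(FPKM + 0.1) and 0.023 with quality weights, and lay between -0.26 without CaP Zn replicate 1 and 0.27 without CaP Zn replicate 2. Nos2 lay between -0.063 without CaP Zn replicate 2 and 0.0072 without CaP Zn replicate 1, Vegfa between -0.099 without CaP Zn replicate 1 and 0.21 without CaP Zn replicate 2, and Acp5 between -0.30 without CaP Zn0.8Mn0.1Li replicate 1 and 0.19 without CaP Zn replicate 2. Il1b lay between -0.13 without CaP Zn0.8Mn0.1Li replicate 1 and 0.38 without CaP Zn0.8Mn0.1Li replicate 2.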

Other observations

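All tests of explanations given here were chosen after the values were seen, except the search for 50-base stretches of Gapdh. The genes most apart in CaP Zn0.8Mn replicate 1, chosen after their values were seen, include the nucleic acid sensors Tlr7 (279 CPM, against 3.26 to 9.63 in the other 5 libraries) and Tlr13 (141, against 2.08 to 3.60). The sphingosine phosphate receptor gene S1pr1 read 40.6 CPM there against 1.02 to 1.94, the integrin gene Itga4 5118 against 271 to 379, and Ahnak, which encodes a very large scaffold protein, 4514 against 377 to 402. At the low end were the actin-binding peptide gene Tmsb10 (6.41 CPM, against 163 to 262), the small ATP synthase subunit gene Atp5k (0.529, against 46.3 to 57.4) and the stress-response genes Ddit3 (16.3, against 155 to 257), Gadd45b (14.7, against 154 to 309) and Nupr1 (5.15, against 92.4 to 98.5).

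Immediate early genes had a median of -1.40 in that library relative to the other 5, and antigen presentation genes -0.88. With all 6 libraries neither list passed for CaP Zn0.8Mn over CaP Zn (median -0.49, adjusted p = 0.0697, and -0.27, adjusted p = 0.22). Ferritin heavy chain (Fth1), which stores iron, differed by 0.42 (SE 0.24) between CaP Zn0.8Mn and CaP Zn and by 0.40 (SE 0.20) between CaP Zn0.8Mn0.1Li and CaP Zn once CaP Zn0.8Mn replicate 1 was left out.

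CaP Zn0.8Mn replicate 1 carries low inflammatory, p53 and ribosomal genes and high mitochondrial mRNAs, while replicate 2 on the same alloy has medians of 0.15, 0.084 and 0.12 relative to CaP Zn for M1, p53 and ribosomal genes. The mitochondrial mRNAs of replicate 2 lie near those of CaP Zn (-0.061), but those of CaP Zn0.8Mn0.1Li lie below both, at -0.25 relative to CaP Zn and -0.36 relative to replicate 2, so a smaller difference in them is not ruled out as one of the alloys. An effect particular to this alloy would have to appear in replicate 2. The slope of its log2 ratios to CaP Zn0.8Mn0.1Li on those of replicate 1 to CaP Zn was 0.0246. This argues against such an effect as the main source of the deviation of replicate 1. A smaller effect, or one on single genes, would hardly move that slope and is not argued against. A manganese effect common to both manganese alloys would cancel in the ratios of replicate 2, so the slope cannot speak to it. The medians above show that M1, p53 and ribosomal genes of replicate 2 did not share the fall seen in replicate 1. A trend with gene length leaves most of the deviation of replicate 1. After the trend was removed, its spread was still 3.41 times the largest of the other 5 libraries. Of the markers of 5 other lineages, 0 reached 50 CPM there with 4-fold over every other library, which argues against a large share of such cells. A smaller share was not excluded by that bound. Summed markers exceeded every other library for endothelial (68.0 CPM, against at most 49.4), lymphoid (41.0, against at most 27.9) and granulocyte or mast cells (13.3, against at most 5.43). They did not for stromal (10.5, against at most 19.4) and erythroid or megakaryocyte cells (6.01, against at most 13.5). A different state of the cells or of the RNA, or an exchanged sample, could each give such a library and stay open.

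CaP Zn replicate 1 leans towards CaP Zn0.8Mn replicate 1, with deviations correlating across genes at 0.273. A carry-over of RNA or reads from that library would leave the genes low in it down by at most -0.022, but their median in CaP Zn replicate 1 was -0.19 (quartiles -0.32 and -0.067), which argues against carry-over alone. A shared trend with gene length could be part of it, but the correlation was still 0.252 after the trend was removed, a value the bounds set for the test left undecided. Without CaP Zn replicate 1, the interferon-stimulated genes of CaP Zn0.8Mn0.1Li over CaP Zn went from -0.18 to -0.061, while M2 markers went from 0.19 to 0.17 and matrix and adhesion genes from 0.09 to 0.053, and none of the 3 lists was called. Whether the interferon difference belongs to the alloy or to that library stays open, and the M2 difference depends less on it.

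Gapdh was low in both CaP Zn0.8Mn libraries (328 and 361 counts, against 6332 and 7007 on CaP Zn and 5747 and 12453 on CaP Zn0.8Mn0.1Li), a gene for which replicate 2 goes with replicate 1. A fall of glycolysis as a whole is argued against by the other glycolytic genes, whose median difference between CaP Zn0.8Mn replicate 2 and the libraries of the other alloys was 0.065 (SD 0.082). Reads could instead be shared out differently among copies of the gene: 0.749 of its 4598 50-base stretches occur in no other gene, which met neither bound of the test. Gm7336 alone shares 1131 stretches. Because the stretches pool all annotated transcripts, that share cannot tell how much of any 1 transcript is unique to Gapdh. The genes that share a stretch with it, most of all Gm13394, summed to 1864 CPM in CaP Zn0.8Mn replicate 2, against 1515 to 1941 in the libraries of the other alloys, and with Gapdh added to 1887 CPM, against 1855 to 2579, while in replicate 1 the sums were 916 and 938 CPM, below both ranges. Because the sums of replicate 2 stayed within those ranges, copies and Gapdh were low together only in replicate 1, and Gapdh reads lost as ambiguous would appear in no gene, whether Gapdh itself changed stays open.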
